A study of Danio rerio with 9 samples.

How the data were processed

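The data were RNA sequencing libraries of whole zebrafish embryos collected 3 hours after fertilization, near the start of transcription from the zygotic genome. There were 3 diploid (control), 3 haploid and 3 tetraploid libraries, each from embryos of a TJH female and a Tu male. Per the labels' protocols, total RNA was extracted with Trizol, samples with an RNA integrity number of 9 or more were used, and libraries followed standard Illumina procedures. Replicates were numbered in accession order within each group, so equal numbers in the 3 groups are also libraries with consecutive numbers in their titles (a library set). The labels do not say that a set shares a clutch or day, and the tests did not pair libraries.

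Each library came with a gene table of FPKM values, fragments per kilobase and per 1e+06 mapped fragments, with the bounds of the interval that Cufflinks gives. FastQC, Trim Galore, HISAT2, Cufflinks and Cuffdiff and the genome build GRCz10 are named in the submitters' processing notes. Versions, the annotation, the strand setting and filters are not given in the sources used here. A further 2 tables deposited by the authors hold Cuffdiff FPKM with 1 pooled value per ploidy, and differ from each other by about 1 factor per ploidy. For each ploidy the median of the second table's values over the first table's was 0.926 in diploids, 1.045 in haploids and 1.024 in tetraploids. These pooled values were used only where they are named as the authors' deposited table.

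The library tables list 30702 loci each. On every one of the 26 reference sequences (25 chromosomes and the mitochondrial genome), locus numbers rose with position, restarted once, and rose again, which splits the loci into a first and a second numbering run. On the 25 chromosomes, between 12.37% and 48.97% of first-run loci had a mean FPKM of at least 1. In the second run the share was between 0 and 0.98%. Second-run genes below this mean were therefore treated as unmeasured, not as silent, and the 44 above it were tested. The unmeasured genes include vox, pou5f3, cdkn1a, ccnb1, krt4, sox19b and tbx16, 7 of the 11 genes chosen in advance as a panel. Of the other panel genes, nanog, klf17 and ndr1 were tested, and hsp70l had a mean FPKM of 0.335, below the filter.

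Depth was not stated. The width of the deposited intervals, read as counting error of 2 standard deviations, implied 2.72 to 5.17 (times 1e+06) fragments per library, and a median of 215.6 to 428.1 fragments per gene with FPKM of at least 1. Of implied values below 20 fragments, 43.2% to 46.3% lay within 0.02 of a whole number, where chance gives 4%. The others did not, so reads per gene were not recovered and no count test was run. An FPKM of exactly 0 can be a failed estimate and is reported as listed at 0.

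The FPKM of each library were scaled by median-of-ratios factors, and 5881 genes with a mean FPKM of at least 1 were tested, 5837 of them from the first numbering run and 44 from the second. A total of 5 genes with a failed status in any library were left out, and 162 tested loci carry several gene symbols, whose reads cannot be assigned to 1 of them. Antisense overlap could not be assessed. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend, all 9 libraries in 1 fit (6 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. A fold change here is on the log2(FPKM + 1) scale, which understates changes of low genes. Levels are scaled FPKM as mean ± SD, n = 3 libraries per group. Nothing in the labels says that libraries came from separate clutches, so p-values measure the spread between these samples, which may be technical.

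A set of 20 gene lists was fixed before the data were examined: early zygotic genes, maternal oocyte-derived transcripts, maternal regulators of genome activation, heat shock and chaperone genes, p53 pathway and apoptosis genes, replication and checkpoint genes, mitosis and cytokinesis genes, nuclear size and import genes, gastrulation movement and adhesion genes, patterning pathway genes, markers of the enveloping layer, the yolk syncytial layer, the germ plasm and late tissues, immediate early and stress genes, glycolysis and energy metabolism genes, cytosolic ribosomal protein genes, mitochondrially encoded genes, histone genes and zinc finger genes. The lists with at least 5 tested genes, 15 of them, were tested with camera in limma at a preset correlation of 0.01, two-sided, adjusted over these lists. Camera with an estimated correlation and fry were alternatives. Of 958 list members in the files, 484 lie in the second numbering run and 303 were tested. The ribosomal list, taken by symbol pattern, holds 40 tested ribosomal protein genes and 4 others, which are 3 S6 kinases and rps19bp1.

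The rule for genes to be named was fixed at the same time. For each comparison they were the 8 largest rises and falls among genes that passed and whose groups did not overlap, leaving out placeholder symbols (872 of the tested genes). Where fewer than 5 passed in a direction, the 5 with the smallest unadjusted p were named. From each list up to 4 passing members, or else the 1 with the smallest p, were named, with the panel. The result for 1 gene named by this rule is not reported here.

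Alternatives were other pseudocounts (0.1 and 5), filters (no filter beyond a mean above 0, and a mean of at least 5), FPKM without further scaling, quantile normalization, limma without the trend, robust empirical Bayes, a fit of the 6 libraries compared, library weights, a block for sets of consecutive library numbers, looser and stricter thresholds, and each library left out in turn. With no filter, second-run loci treated as unmeasured also enter the lists, so a change under that setting need not reflect the measured genes. The scripts were tested on simulated data made from the 5881 genes, with 200 genes changed in each of 5 simulations. For haploid against diploid, 9.55% of genes changed 1.5-fold, 54.9% of genes changed 2-fold and 92.7% of genes changed 4-fold were recovered. The shares were 9.85%, 51.6% and 91.2% for tetraploid against diploid, and 9.55%, 49.6% and 93.3% for tetraploid against haploid. False calls averaged 6.4, 6.4 and 4.8 per simulation. A list of 17 genes shifted 1.2-fold was called in 4, 5 and 5 of 5 simulations, and 0 of 70 unchanged lists were called in each comparison. Simulated genes varied independently, with the same spread in all libraries. These counts therefore do not show how often camera calls unchanged lists whose genes vary together. Estimated correlations were 0.321 in the early zygotic list and 0.444 in the ribosomal list.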

Results

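The transcriptomes of diploid, haploid and tetraploid zebrafish embryos were compared at 3 hours after fertilization, in a study of cell size and gastrulation movements. Embryos of different ploidy differ in cell size, and at this stage most RNA is still maternal. The 9 libraries, 3 per ploidy, had 5395 to 5921 loci with an FPKM of at least 1. Mitochondrial loci took 14.74% to 26.75% of the summed FPKM.

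**Figure D1:**
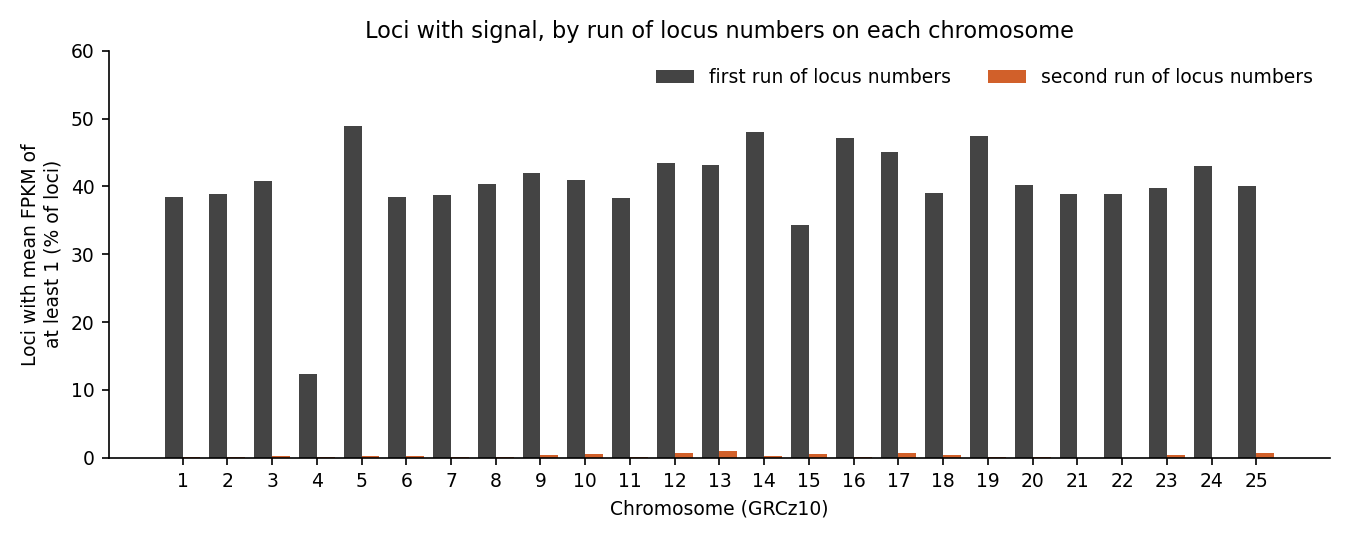
Share of loci (%) with a mean FPKM of at least 1 over the 9 libraries, for each of the 25 chromosomes (GRCz10), with dark bars for the first and orange bars for the second run of locus numbers. First-run shares lie between 12.37% (chromosome 4) and 48.97%, and second-run shares between 0 and 0.98%.

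Libraries did not group by ploidy. Tetraploid replicate 3 stood apart, with correlations of 0.9163 to 0.9305 with the other libraries, against 0.9502 to 0.9851 among the other 28 pairs. The first principal component, with 35.7% of the variance, separated this library from the rest. Among the 8 other libraries, pairs of the same ploidy had a mean correlation of 0.9673, and pairs of different ploidy had 0.9681 within and 0.9691 across sets of consecutive library numbers. No pair of libraries was identical. The maternal transcription factor nanog, on chromosome 24 from 12689785 to 12694862, had 876.5 ± 59.9 scaled FPKM in diploids, 908.8 ± 32.6 in haploids and 1003 ± 136 in tetraploids (SD, n = 3 each).

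**Figure D2:**
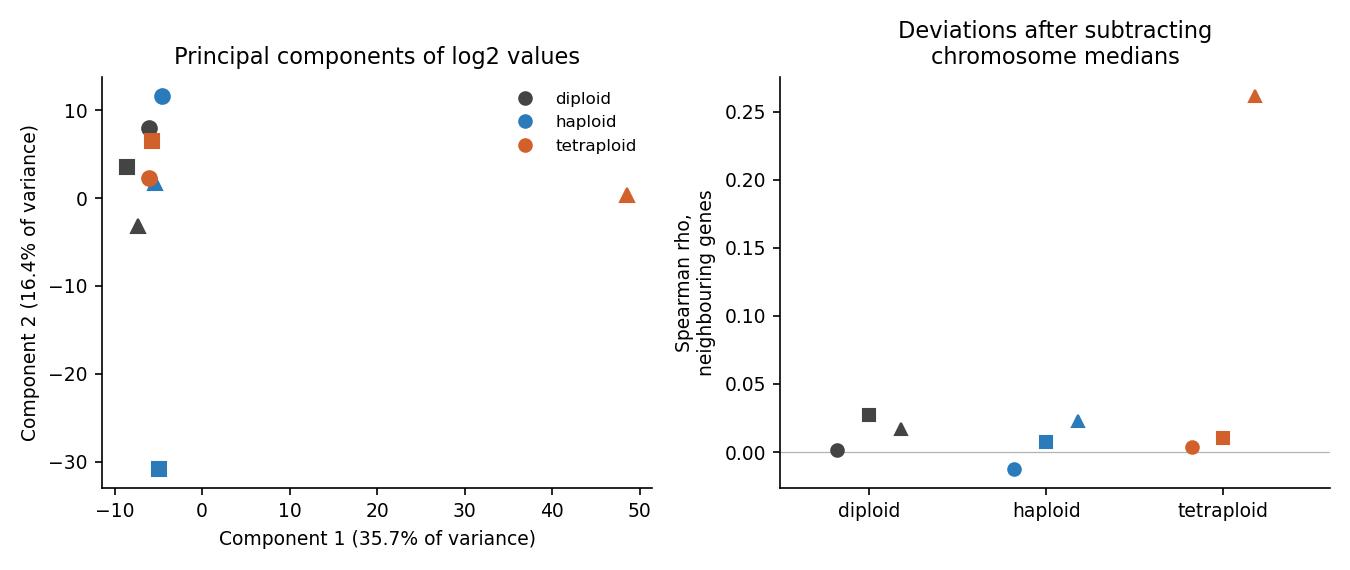
Left, principal components 1 (35.7% of variance) and 2 (16.4%) of the log2 values, in arbitrary units, with color for ploidy and circle, square and triangle for replicates 1, 2 and 3. Right, Spearman rho between neighbouring genes of each library's deviations from the other libraries after subtracting chromosome medians, which is 0.262 in tetraploid replicate 3 and -0.0126 to 0.0273 in the others.

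The first comparison asked how embryos with a single genome set differ from the diploid control. Early zygotic genes, which are among the first transcribed from the embryo's own genome, were lower in haploids as a list, with 11 of 12 tested members negative and a median log2 change of -0.54 (adjusted p = 2.8e-05 by camera, adjusted p = 0.308 with an estimated correlation). The largest difference was in klf17, a Krüppel-like transcription factor, with 30.4 ± 25.8 scaled FPKM in diploids and 7.0 ± 9.70 in haploids. The homeobox genes irx7 (named outside the rule) and mxtx2 differed by log2 values of -2.12 and -1.46. Immediate early and stress genes were also lower as a list (8 of 9 negative, median -0.20, adjusted p = 0.00157; adjusted p = 0.19 with an estimated correlation), with gadd45bb, a stress-inducible gene, at 14.3 ± 8.20 in diploids and 1.72 ± 2.26 in haploids. Cytosolic ribosomal protein genes were lower by a median of -0.23, with 40 of 44 negative (adjusted p = 1.58e-06; adjusted p = 0.613 with an estimated correlation).

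By fry 0 of these lists passed (adjusted p = 0.694, 0.619 and 0.741). Adjusted over the list alone, 2 stress genes passed, gadd45bb and mych, a myc family gene, and 0 early zygotic or ribosomal genes did. Over all genes tested, 0 of each list passed. Diploid replicate 1 had the highest early zygotic score, 1.33 log2 units above the mean of the libraries, against -0.26 and 0.25 in the other diploids, 0.46, -0.94 and -0.75 in haploids and 0.09, -0.18 and -0.00159 in tetraploids. The same library was highest in markers of the enveloping layer and yolk syncytial layer, with grhl3 at 4.95 ± 7.11 in diploids and 0.627 ± 0.573 in haploids, and mxtx2 at 4.99 ± 4.83 and 1.05 ± 1.43. These marker lists had only 3 and 2 tested members. mxtx2 is also a member of the early zygotic list, so its value is not a separate observation. Without diploid replicate 1 the early zygotic list had an adjusted p of 0.0473 and a median of -0.32 over the 10 members that still passed the filter, within a range of 5.47e-10 to 0.694 across its alternatives. Its median was -1.08 without diploid replicate 2, -0.86 without diploid replicate 3 and -1.28 without haploid replicate 1. The size of this median also depended on the settings, at -1.35 with a pseudocount of 0.1, -0.26 with a pseudocount of 5, -1.03 with library weights, -0.30 with no filter and -0.28 with a mean FPKM of at least 5. Without diploid replicate 2, whose ribosomal score was 0.648, the ribosomal call was lost (adjusted p = 0.857, median -0.03). Without haploid replicate 3 the stress list was lost (adjusted p = 0.0615), though its median stayed negative over single libraries left out (-0.448 to -0.141). The ribosomal median was -0.36 without diploid replicate 3, -0.38 without haploid replicate 1 and -0.13 without haploid replicate 2. The stress median was -0.38 without diploid replicate 2 and -0.45 without haploid replicate 2. The stress call was lost with a mean FPKM of at least 5 (median -0.13, adjusted p = 0.0722). The ribosomal call was lost with no filter (median -0.09, adjusted p = 0.25). That setting lets in second-run loci treated as unmeasured, 49 of the 94 ribosomal loci listed, so this loss says little about the measured genes. The stress median was -0.10 with a pseudocount of 5, -0.11 with no filter and -0.44 with library weights, and the ribosomal median was -0.15 with library weights.

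No single gene passed in haploids. Limma called 0 of 5881 genes, with 81 at an unadjusted p under 0.05, fewer than the 294 expected by chance, and a smallest adjusted p of 1. The spread was pooled over all 9 libraries, with tetraploid replicate 3 among them (median absolute deviation 0.426 against 0.135 to 0.235 in the others). A count below chance can therefore come from a spread too wide for this comparison. In a fit of the 6 libraries compared, 0 genes were called as well. Of the genes, 505 had groups that did not overlap (8.59%, where chance gives 10%), and 99.15% lay within 2-fold. Among the smallest p values, none of them passing, were those of ddt, with 42.2 ± 11.3 in diploids and 65.1 ± 12.2 in haploids, and syncripl, an RNA-binding protein gene, with 45.4 ± 5.20 and 63.8 ± 14. The genes ccpg1 and dscama had log2 differences of 0.64 ± 0.198 and 0.64 ± 0.238 (SE). vgll4b was listed at 0 in all diploids, with 4.49 ± 2.72 in haploids. On the lower side, tnfsf10l4 had a log2 difference of -0.65 ± 0.188, msi2a of -0.49 ± 0.142, f3b of -0.53 ± 0.16 and mych of -1.02 ± 0.316 (SE, limma, adjusted p = 1 for each).

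The other lists did not pass in haploids. Mitochondrially encoded genes had 9 of 9 members positive (median 0.16, adjusted p = 0.0908), with mt-cyb, cytochrome b, at 4963 ± 332 in diploids and 6218 ± 1070 in haploids. Glycolysis and energy genes had 12 of 15 negative (adjusted p = 0.0908), with pgk1 at 23.6 ± 3.95 and 16.9 ± 5.67. The mitochondrial difference rested on haploid replicate 2, whose score was 0.724 against -0.02 and 0.0356 in the other haploids, and without it the median was -0.04 (adjusted p = 0.962). Both lists passed without haploid replicate 1, where 5 lists were called. Mitochondrial genes passed without diploid replicate 2, and histone genes became testable and passed as lower without diploid replicate 1. Adjusted p values were 0.311 for mitosis and cytokinesis genes, 0.706 for heat shock genes, p53 pathway genes and genome activation regulators. They were 0.724 for maternal transcripts, replication, gastrulation movement, patterning and zinc finger genes, and 0.941 for nuclear import genes. In gastrulation movement genes the median was 0.08 and the mean was -0.09, opposite in sign, as they were in patterning genes (-0.01 and 0.01). In diploids and haploids in that order, members with the smallest p were birc5b (87.3 ± 6.28 and 65.2 ± 4.64), npm2a, a nucleoplasmin gene (46.3 ± 4.42 and 36.6 ± 4.76), rif1 (97.7 ± 1.05 and 108.8 ± 5.11), hsp90ab1 (319 ± 11.8 and 265.8 ± 45.1). Others were zp3b (53.4 ± 8.99 and 61.4 ± 5.01), ccnt2b (160.6 ± 3.24 and 179 ± 8.33), sesn1 (18.8 ± 3.94 and 16.2 ± 2.07), wnt11 (1.90 ± 1.72 and 0.461 ± 0.461), rps21 (144 ± 21.2 and 118.7 ± 9.13) and znf513 (11.2 ± 0.475 and 7.37 ± 2.74). The lists of enveloping layer, yolk syncytial, germ plasm, histone and late tissue genes had 3, 2, 4, 4 and 0 tested members and no list test. Among their members tdrd6, a germ plasm component, had 23.2 ± 1.26 in diploids and 28.5 ± 3.53 in haploids, and hist2h3c had 3.08 ± 0.714 and 1.80 ± 0.519. ndr1, a Nodal ligand gene, had 1.54 ± 0.621 and 1.15 ± 0.476.

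**Figure D3:**
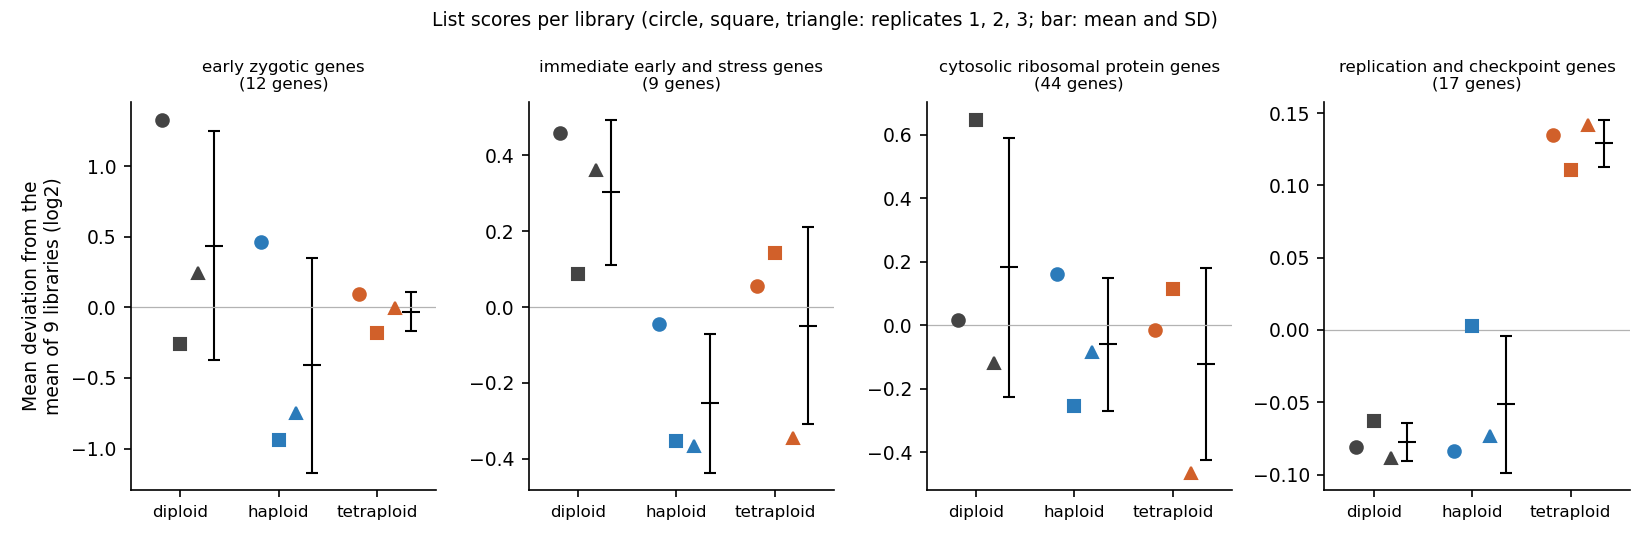
Mean deviation of each library from the mean of the 9 libraries (log2) for 4 gene lists, with circle, square and triangle for replicates 1, 2 and 3 and bars for mean and SD (n = 3 libraries). The replication and checkpoint score is 0.111 to 0.142 in the 3 tetraploid libraries and at most 0.00256 in the others, and the early zygotic score is highest in diploid replicate 1 (1.33).

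The second comparison asked how a doubled genome content changes the diploid transcriptome. Replication and checkpoint genes were higher in tetraploids as a list, with 16 of 17 tested members positive and a median of 0.21 log2 units (1.16-fold, adjusted p = 0.00243 by camera, adjusted p = 0.106 with an estimated correlation). They include chek1, the checkpoint kinase that slows the cell cycle near genome activation, at 29.9 ± 0.972 in diploids and 42.8 ± 9.47 in tetraploids. Log2 differences were 0.44 for pola1, a DNA polymerase alpha subunit, 0.34 for topbp1 and 0.27 for fen1. A single gene passed, ankdd1a, which encodes an ankyrin repeat and death domain protein. It fell from 15.0 ± 0.555 to 4.97 ± 0.585 scaled FPKM (log2 -1.43, SE 0.155, limma adjusted p = 0.0286), lower in each of the 3 tetraploid libraries than in every diploid and haploid library.

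With FPKM as deposited the replication median was 0.10, where the median of all genes was itself -0.112, against -0.00456 after scaling. The replication median was 0.14 with a pseudocount of 5 and 0.04 with no filter, where the call was lost (adjusted p = 0.153). With no filter, second-run loci treated as unmeasured enter this list, 21 of its 38 loci. By fry the replication list had an adjusted p of 0.00462, and 0 of its members passed, adjusted over the list alone or over all genes. The ankdd1a locus spans chromosome 7 from 13329536 to 13452776. In the authors' deposited tables the pooled ankdd1a values were 35.5, 38.6 and 18.7 FPKM for diploid, haploid and tetraploid in the first table and 32.8, 40.5 and 18.8 in the second. The relative fall in tetraploids was smaller in these pooled values than in the scaled FPKM of the libraries. The ankdd1a call was lost in 13 of 24 alternatives, which gave adjusted p values of 0.00477 to 0.315 and log2 values of -1.58 to -1.01. It was lost without each of the libraries in turn apart from tetraploid replicate 3 (0.0427 without it). It was also lost with the block for library sets (0.272) and in a fit of the 6 libraries compared (0.308). Without diploid replicate 1 the 1 gene called was dut, at 71.6 in that library and listed at 0 in the other diploids.

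**Figure D4:**
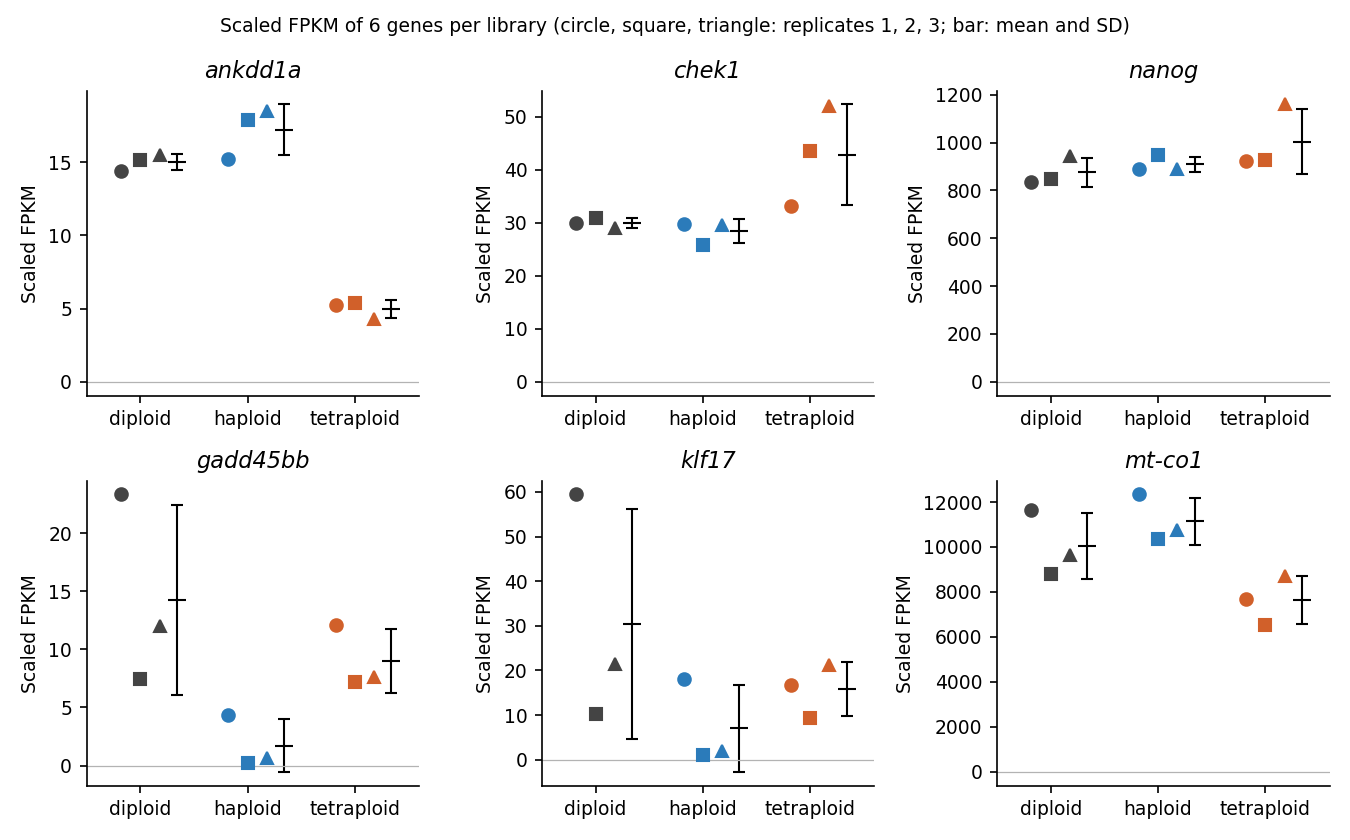
Scaled FPKM of 6 genes in each library, with circle, square and triangle for replicates 1, 2 and 3 and bars for mean and SD (n = 3 libraries). ankdd1a lies at 4.97 ± 0.585 in tetraploids and 15.0 ± 0.555 in diploids, and klf17 and gadd45bb vary widely among diploids.

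Cytosolic ribosomal protein genes were lower as a list in tetraploids (34 of 44 negative, median -0.29, adjusted p = 0.00243; adjusted p = 0.769 with an estimated correlation), with 0 passing adjusted over the list alone. Their call was lost without diploid replicate 2 (median 0.0017, adjusted p = 0.802) and without tetraploid replicate 3, whose score was -0.464 (median -0.11, adjusted p = 0.072). It was also lost with library weights (median -0.08, adjusted p = 0.329) and by fry (0.787). With no filter, which adds second-run loci treated as unmeasured, it was lost too (median -0.07, adjusted p = 0.153). The member with the smallest p, rps19bp1, is not a ribosomal protein gene and had 39.2 ± 1.15 in diploids and 26.3 ± 8.70 in tetraploids. Across all genes limma called 1, with 288 at an unadjusted p under 0.05 (294 by chance), and 676 genes had groups that did not overlap (11.5%, where chance gives 10%). Values that did not pass included log2 differences of 1.03 ± 0.183 for rarga, a retinoic acid receptor, 0.92 ± 0.208 for bloc1s2, 0.75 ± 0.206 for med19b of the Mediator complex, 0.49 ± 0.136 for supt16h and 0.67 ± 0.188 for clybl. Lower values were -0.99 ± 0.203 for arpc3, a subunit of the Arp2/3 actin complex, -1.13 ± 0.252 for tspan13a, -0.93 ± 0.224 for oafb and -0.72 ± 0.182 for zbtb47a (SE).

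The remaining lists did not pass in tetraploids against diploids under the settings used for the reported tests. Stress genes passed as lower with no filter, and early zygotic and stress genes as lower with a block for library sets, where 4 lists were called. Zinc finger genes passed without diploid replicate 1, early zygotic and stress genes without diploid replicate 2, and mitosis genes without tetraploid replicate 3, with 3, 3 and 2 lists called. The early zygotic median was -0.51 (8 of 12 negative), against -0.54 in haploids. The stress median was -0.40 (7 of 9 negative), against -0.20 in haploids. Camera gave adjusted p values of 0.114 for immediate early and stress genes and for zinc finger genes, 0.142 for genome activation regulators, and 0.282 for early zygotic genes. They were 0.393 for mitochondrially encoded genes, 0.431 for mitosis genes, 0.528 for nuclear import genes, and 0.818 for maternal transcripts. The highest were 0.885 for heat shock genes, 0.966 for p53 pathway and glycolysis genes and 0.986 for gastrulation movement and patterning genes. By fry, genome activation regulators (0.0237; 9 of 13 positive, median 0.16) and nuclear import genes (0.0451; 5 of 9 positive, median 0.07) also passed. The nuclear import score was -0.0806 in tetraploid replicate 3, against 0.0845 and 0.0631 in the other tetraploids. Among members, setdb1a, a histone methyltransferase, had 25.5 ± 1.84 in diploids and 41.2 ± 11.2 in tetraploids. kpnb1, importin beta, had 39.7 ± 1.79 and 54.3 ± 10.4. Both genes lie on chromosome 19, where tetraploid replicate 3 had a median deviation of 0.297 from the other libraries. Over single libraries left out their log2 differences ranged from 0.437 to 0.782 and from 0.295 to 0.568. The median and mean differed in sign in the lists of gastrulation movement (0.05 and -0.11), glycolysis (0.02 and -0.03) and p53 pathway genes (-0.01 and 0.01). In diploids and tetraploids in that order, gadd45ba had 3.56 ± 2.12 and 0.492 ± 0.302, lhx8a 11.6 ± 0.713 and 15.5 ± 1.32, hspe1 10.8 ± 2.35 and 17.8 ± 1.15, and casp8 31.2 ± 2.16 and 22.2 ± 10.1. Likewise nek2 had 112.2 ± 6.26 and 152.3 ± 36.4, cxcr4b 8.35 ± 8.74 and 2.55 ± 1.35, smad4a 22.4 ± 0.885 and 15.7 ± 3.25, gpia 14.4 ± 1.83 and 10.2 ± 2.29, and znf410 2.26 ± 0.079 and 1.18 ± 0.461. Of the marker lists without a test, apoeb had 3.70 ± 4.89 and 1.06 ± 0.588, and h2afvb 806.2 ± 65.9 and 901.2 ± 148.

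The third comparison set the ends of the ploidy series against each other, tetraploid against haploid. The replication and checkpoint list was again higher in tetraploids (13 of 17 positive, median 0.22 log2 units, adjusted p = 0.0331; adjusted p = 0.247 with an estimated correlation). In this list chek1 had 28.4 ± 2.26 in haploids and 42.8 ± 9.47 in tetraploids. ankdd1a fell from 17.2 ± 1.74 to 4.97 ± 0.585 (log2 -1.61, SE 0.155, limma adjusted p = 0.0101). Mitochondrially encoded genes had 8 of 9 members negative, a median of -0.29 and an adjusted p of 0.0571, with mt-co1, cytochrome oxidase subunit 1, at 11150 ± 1050 in haploids and 7633 ± 1080 in tetraploids. The mitochondrial score was -1.03 in tetraploid replicate 3 against 0.201 and -0.0927 in the other tetraploids, and 0.724 in haploid replicate 2. Without the first the median was -0.26 (adjusted p = 0.108), and without the second -0.14 (adjusted p = 0.679).

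By fry the replication list had an adjusted p of 0.0132, and 0 of its members passed, adjusted over the list alone or over all genes. Its call was lost without haploid replicate 1 (0.0717), haploid replicate 3 (0.0651) or tetraploid replicate 2 (0.0654), within a range of 0.0121 to 0.742 over its alternatives. Over single libraries left out its median stayed between 0.164 and 0.242. With FPKM as deposited the list median was 0.12, where the median of all genes was -0.0915. The list median was 0.10 under quantile normalization (adjusted p = 0.169), and the call was also lost with a mean FPKM of at least 5 (0.0611). With no filter, which adds second-run loci treated as unmeasured, the median was -0.00124, turned in sign (0.742). Lists called numbered 2 without haploid replicate 1 (early zygotic and mitochondrial), 1 without haploid replicate 3 (mitochondrial), 2 without tetraploid replicate 1 (replication and mitochondrial), 0 without tetraploid replicate 2 and 2 without tetraploid replicate 3 (replication and mitosis). The ankdd1a call was lost without diploid replicate 1, haploid replicate 2 or 3, or tetraploid replicate 1 or 2 (adjusted p from 0.0517 to 0.129). It was also lost with the block for library sets (0.118) and in a fit of the 6 libraries compared (0.254), and the lowest adjusted p was 0.00183. Over single libraries left out the ankdd1a log2 value stayed between -1.69 and -1.53. Limma called this 1 gene of 5881, with 454 at an unadjusted p under 0.05 (294 by chance), and 809 genes had groups that did not overlap (13.8%, where chance gives 10%).

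Genes with the smallest p that did not pass included TPM1, tropomyosin, with 58.6 ± 5.13 in haploids and 88.6 ± 7.12 in tetraploids, f3b with 12 ± 1.53 and 20.1 ± 2.54, tmem203 with 13.4 ± 1.51 and 22.1 ± 1.26, and josd2 with 21.9 ± 3.20 and 34.2 ± 3.35. On the lower side the tetraspanin gene cd82b had 86.9 ± 4.61 and 47.1 ± 9.00, ydjc 15.2 ± 1.86 and 7.99 ± 1.42, mmd 17.4 ± 3.97 and 8.81 ± 1.31, and slc44a1a 30.4 ± 2.96 and 12.7 ± 3.98. Adjusted over the list alone, 1 gene passed in each of 6 lists. These were wnt8a in the early zygotic and patterning lists (9.52 ± 0.549 and 16 ± 2.79), lhx8a among maternal transcripts (10.2 ± 0.911 and 15.5 ± 1.32), setdb1a among genome activation regulators (22.7 ± 1.66 and 41.2 ± 11.2), gadd45bb among stress genes (1.72 ± 2.26 and 9.00 ± 2.72) and tdrd6 among germ plasm markers (28.5 ± 3.53 and 19.1 ± 3.06). The wnt8a locus also carries the symbol BX927327.1.

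No further list passed between tetraploids and haploids under the settings used for the reported tests. Mitochondrial genes passed with a pseudocount of 0.1, FPKM as deposited, the 6 libraries compared or the library-set block, early zygotic genes with the 6 libraries compared, and mitosis genes with library weights. The adjusted p values were 0.176 for mitosis genes, 0.268 for early zygotic genes, 0.3 for zinc finger genes, and 0.488 for genome activation regulators and glycolysis genes. They were 0.575 for heat shock genes, 0.624 for maternal transcripts, nuclear import and stress genes, and 0.716 for p53 pathway, gastrulation movement, patterning and ribosomal protein genes. The median and mean differed in sign in the ribosomal (0.02 and -0.06), maternal (-0.01 and 0.07) and nuclear import lists (-0.02 and 0.04). Members with the smallest p had, in haploids and tetraploids, 65.2 ± 4.64 and 110.1 ± 30.8 for birc5b, 36.6 ± 4.76 and 51.6 ± 2.30 for npm2a, 10 ± 4.24 and 17.8 ± 1.15 for hspe1, and 2.88 ± 0.719 and 6.42 ± 2.81 for pmaip1. Next came 26 ± 3.10 and 20.5 ± 3.88 for dvl2, 16 ± 1.78 and 10.2 ± 2.29 for gpia, 110 ± 25 and 77.3 ± 4.24 for rps2, and 11.6 ± 1.44 and 15.8 ± 1.18 for znf76. The panel genes klf17 and ndr1 had 7.0 ± 9.70 and 15.8 ± 5.97, and 1.15 ± 0.476 and 0.797 ± 0.277.

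The fold changes of haploids and of tetraploids against the shared diploid libraries were correlated across the 5881 genes (Pearson r = 0.404, Spearman rho = 0.278, covariance 0.0381). Genes are not independent replicates, and both changes share the 3 diploid libraries. Simulated unchanged groups with equal spread gave r = 0.501, rho = 0.472 and a covariance of 0.0427, and with a spread estimated per library r = 0.307, rho = 0.285 and a covariance of 0.0217. The excess covariance was -0.00469 in the first case and 0.0164 in the second, so its sign depends on how the spread is modelled. No split of the 3 diploid libraries leaves 2 in each part, so they were not split, and part of any excess may come from the shared controls.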

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

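The first numbering run alone, loci with 1 symbol, failed estimates kept, the ribosomal list without its 4 other genes, and leaving out diploid replicate 1 and tetraploid replicate 3 together were tests chosen after the results were seen. The 92 results for named genes were compared with the alternatives 2171 times in all. In 2144 of these comparisons direction and side of the threshold were kept, 21 lost the call and 6 turned or reached 0. Only ankdd1a had a call to lose. It was lost in 13 of 24 alternatives in tetraploids against diploids and in 8 of 24 against haploids. For the other named genes, keeping the side of the threshold means that they stayed uncalled. The cause was not tested unless given. Depth limits low genes, and tetraploid replicate 3 had the fewest implied fragments (2.72, times 1e+06). FPKM as deposited gave a median log2 change of all genes of -0.112 in tetraploids against diploids, against -0.00456 after scaling. Robust empirical Bayes was not run for lists, since camera has no such setting.

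Genes called in haploids against diploids went from 0 to 1 (dut) without diploid replicate 1 and with it and tetraploid replicate 3 left out (range 0 to 1 over single libraries). In tetraploids against diploids the 1 gene became 0 with a pseudocount of 5, FPKM as deposited, the 6 libraries compared or the library-set block, 2 with no filter (ankdd1a and elovl8a), and 0 to 1 over single libraries left out. In tetraploids against haploids it became 0 with the 6 libraries compared, the library-set block or 2 libraries left out, and 0 to 1 over single libraries. With fewer samples the residual degrees of freedom also fall.

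Lists called in haploids against diploids, 3, became 0 with an estimated correlation and 0 by fry, and 2 to 5 over single libraries left out. With the library-set block the early zygotic, stress and ribosomal lists stayed called (camera at the preset correlation, adjusted p = 8.12e-09, 0.000325 and 4.41e-07). In the 2-library omission the early zygotic list was lost (adjusted p = 0.13). In tetraploids against diploids the 2 lists became 1 with no filter (stress genes), 1 with library weights, 4 with the library-set block (early zygotic and stress genes added) and 0 with an estimated correlation, and 2 to 3 over single libraries. In tetraploids against haploids the 1 list became 2 with a pseudocount of 0.1, 0 with no filter, 0 with a mean of at least 5, 2 with FPKM as deposited, 0 with quantile normalization, 3 with the 6 libraries compared, 2 with library weights, 2 with the block and 0 with an estimated correlation, and 0 to 2 over single libraries. With 2 libraries left out the count stayed at 1, but the replication call was lost (adjusted p = 0.0555) and mitosis genes took its place.

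The block joins libraries with consecutive numbers (1 to 3, 4 to 6, 19 to 21). Correlations of deviations were -0.11 to 0.234 within these sets and -0.133 to 0.228 across them. These ranges over all genes overlap, which does not exclude a set effect on single lists. The early zygotic score was highest in replicate 1 and lowest in replicate 2 of each ploidy. The fold change correlation ranged from 0.309 to 0.542 over single libraries left out and was 0.497 with 2 left out. Directions that turned or reached 0 were nanog in haploids against diploids (-0.0276) and mt-cyb (0) and mt-co1 in tetraploids against haploids (0), all under quantile normalization; h2afvb with 2 libraries left out (-0.0453); and, without diploid replicate 1, apoeb (range -1.21 to 0.105 over single libraries) and klf17 (-1.2 to 0.0155) in tetraploids against diploids. The ribosomal list there ranged from -0.414 to 0.0017, the latter without diploid replicate 2. The replication list in tetraploids against haploids turned to -0.00124 with no filter, which adds second-run loci treated as unmeasured.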

Other observations

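The tests of the 3 patterns below were chosen after the patterns were seen; the counts over other splits of the libraries were planned beforehand. Abundant nuclear transcripts, named here after their values were seen, are given as means over the 9 libraries, and their order can differ between ploidies. They included the claudin gene cldnd at 2800 ± 766 scaled FPKM (SD over the 9 libraries), the RNA-binding protein genes hnrnpa0l (1990 ± 149) and hnrnpabb (1870 ± 155) and ccnb2, cyclin B2 (1370 ± 193). The histone variant genes h3f3d (987 ± 213) and h2afva (798 ± 52.5), nanog (929 ± 95.1), the maternal zinc finger gene cth1 (924 ± 145) and gmnn, which encodes the licensing inhibitor geminin (895 ± 269), were also among the 40 most abundant loci. Second-run genes treated as unmeasured could not enter this ranking, however abundant their transcripts were. Chromosome 4 had the lowest share of first-run loci with a mean FPKM of at least 1, 12.37% of 1471, against 34.31% on chromosome 15, the next lowest.

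Loci of the second numbering run carry almost no signal. Of ribosomal protein genes, whose products form 1 particle, 40 of 40 in the first run and 0 of 42 in the second had a mean FPKM of at least 1 (Fisher's exact test, two-sided, p = 2.41e-24), which argues against silence of these genes at this stage. A candidate explanation is that the signal of 1 strand is missing from the tables: mt-nd6, the mitochondrial protein gene on the other strand, is in the second run and listed at 0 in all 9 libraries, while the lowest of the other 9 mitochondrial protein loci, mt-nd5, has a mean of 483.3. The authors' deposited pooled tables show the same, with 6581 to 6665 of 15163 first-run loci and 84 to 114 of 15537 second-run loci at 1 or more. The step that lost the signal was not identified.

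Tetraploid replicate 3 departs from the other libraries in stretches of neighbouring genes. Lower depth does not account for it, since over 618 genes with at least 1000 implied fragments in every library its median absolute deviation was 0.397, against 0.075 to 0.135 in the others. Whether its label is right stays open. Its highest correlation with a diploid or haploid library, 0.9305, is no guide, since correlation among the other libraries does not follow ploidy (mean 0.9673 within, 0.9681 and 0.9691 between). In this library ankdd1a (4.30 against 5.23 and 5.38 in the other tetraploids and 14.4 or more elsewhere) runs as the label says. So does the replication score (0.142 against 0.135 and 0.111, and at most 0.00256 elsewhere). Both were picked out with this library among the tetraploids, so they are no fully independent check, though both calls also stood without it. Whole chromosomes at another dose cannot be the whole cause, because the rank correlation between neighbouring genes stayed at 0.262 after chromosome medians were subtracted, against -0.0126 to 0.0273. Base composition of the transcripts may contribute and was not tested, and its loci of up to 2 kb had a median deviation of -0.392 against -0.146 to 0.134.

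Early zygotic genes were lower in haploids by camera at the preset correlation, though not with an estimated one (adjusted p = 0.308) or by fry (0.694). Against the same diploids the list was also lower in tetraploids without passing (median -0.513, 8 of 12 negative, camera adjusted p = 0.282). A negative median was thus not particular to haploids, and ploidy itself remains an untested candidate. The median in haploids was -0.541 over 12 genes, and without diploid replicate 1 it was -0.315 over the 10 that still passed the filter (adjusted p = 0.0473). Leaving out tetraploid replicate 3 as well left it at -0.319 (0.13), no further loss of the difference. These fits therefore did not tell a chance high library and ploidy apart. Libraries collected at slightly different times may also contribute. Within groups the score was compared with that of 13 other early expressed markers. Pearson r was 0.838 (exact permutation p = 0.037 over 216 orders within groups) and Spearman rho 0.75 (exact permutation p = 0.0648). The relation did not pass after adjustment (adjusted permutation p = 0.0648 for both), and r was 0.559 without diploid replicate 1 and haploid replicate 1. A first permutation across all 9 libraries gave a smaller p and was replaced after its value was seen, because it ignored the groups. A collection time that differed between ploidies cannot be told apart from the groups, since the labels give 1 stage. A difference shared by the libraries of a set is taken up by the block. Within each set the haploid score was below the diploid score (0.463 and 1.33, -0.939 and -0.263, -0.751 and 0.246). With the block the list passed in haploids by camera at the preset correlation (median -0.541, adjusted p = 8.12e-09). The estimated correlation and fry were not run with the block.

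For each comparison the 6 libraries make 10 splits, too few for a share under 0.05. Genes called in haploids against diploids were 0 in the real split and at most 1 in the others, with as many in 10 of 10 splits. In tetraploids against diploids they were 1 and 0, with as many in 1 split, and in tetraploids against haploids 1 and 1, with as many in 3. Lists called were 3 and at most 3 (2 splits with as many), 2 and 4 (5 splits), and 1 and 3 (6 splits), in the same order.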
